A study of Arabidopsis thaliana with 12 samples.

How the data were processed

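Whole seedlings grown on MS plates gave total RNA, which was amplified, labelled with biotin and hybridized to 1-colour arrays with Affymetrix probe set names, 1 array per biological replicate. The deposited values are log2 values: per the labels the authors used RMA, which corrects background, quantile-normalizes arrays and summarises probes, without a stated version. The values themselves show that each probe set was then centred on its own median over the 12 arrays, with row medians of 0 within 5e-07. Base 2 is that of RMA and is not written in the deposited table. Centring removed the expression levels, of which only broad classes (2 to 4, 4 to 8, and 8 or over) could be read, from the spacing of the stored numbers, for all but 1254 probe sets. No counts or depths exist for arrays, so the number of arrays limits the precision.

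The table held 22810 probe sets, of which 64 control probe sets were set aside and 22746 tested. A gene table paired 13513 of these with exactly 1 gene and 503 with several, and the other 8730 were not in it. Symbols came from a RefSeq table, in which 77 of the 13513 had no match. Gene names were printed only for probe sets with exactly 1 gene. PR1, PR2, PR5, BRCA1 and SMR7, which were among the genes to be named in every group, were paired with no such probe set. No result is given under their names, but probe sets outside the gene table may measure them.

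Groups, comparisons, gene lists and the rule for named genes were set before the data were examined. R 4.3.3 with limma 3.58.1 fitted 1 mean per group over all 12 arrays (8 residual and 8.82 prior degrees of freedom) and moderated the variances. The 6 contrasts were INA, BLM and BLM+INA each against control, BLM+INA against BLM, BLM+INA against INA, and the interaction, which is BLM+INA minus BLM minus INA plus control. Tests were two-sided with Benjamini-Hochberg adjustment per contrast over the 22746 probe sets, and the threshold was an adjusted p of 0.05. Named genes were the 10 largest rises and the 10 largest falls past the threshold (5 for the comparisons with BLM and with INA), where the arrays of both groups did not overlap for comparisons with control, which chance gives for 10% of probe sets. Up to 4 members of each list and PDF1.2a were named besides.

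Of 14 lists with 325 genes, 41 genes were named, and the 9 lists with at least 3 named genes were tested with camera (preset correlation 0.01) in the 6 contrasts, 54 tests adjusted together. The list tests used 13286 genes, with the mean over probe sets for the 144 genes that had more than 1, in a fit of their own, so adjusted p values of genes and of probe sets differ slightly. With an estimated correlation, calls held for the salicylic acid list in BLM+INA against control, BLM and INA and in the interaction, for the endoplasmic reticulum list against BLM and in the interaction, for the abscisic acid list against BLM, for the xenobiotic list in BLM+INA against control and against INA, and for the mitosis list and the root markers in each comparison of a BLM group with control or INA. The other set calls were lost. The held calls had adjusted p values from 0.0266 to 0.0495 with the estimated correlation, larger than those printed below with the preset correlation. The overlap of INA and BLM calls was compared with independent lists and with 50 simulations of unchanged groups against the shared controls.

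Alternatives were centring of each array, quantile normalization of the centred values, array weights, robust variances, unmoderated variances, the replicate number as a block, probe sets with 1 gene only, the compared groups only, a stricter threshold of 0.01, a 2-fold minimum, the linear scale for the interaction, fry, an estimated correlation, and each array left out in turn. Some plans could not be run as written on centred values. The filter on a mean level under 5 was replaced by one on a median level under 4, read from the spacing of the stored numbers (4773 probe sets). The brightest probe set of a gene was replaced by the mean, and the trend of variance with level was left out. The linear scale was computed from centred values, as 2 to the power of the value.

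The model was tested on simulated data with 200 changed of 22746 probe sets in 5 runs. For BLM against control, 79% of 1.5-fold and 99.9% of 2-fold changes were recovered, with 6.13% and 5.82% false calls. For the interaction, 15.6% of 1.5-fold and 95.8% of 2-fold changes were recovered, with 6.5% and 5.7% false calls. Of 200 random lists, 5% had a camera p under 0.05. Genes picked at random need not change together, so this rate does not cover lists whose members do. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.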

Results

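Wild-type Arabidopsis thaliana seedlings were profiled on 12 arrays in 4 groups of 3 biological replicates: an untreated control, INA at 10 µM, BLM at 4 µg/ml, and BLM+INA at the same doses. The series title calls the agents a DNA-damaging agent and an immune inducer and states synergy on defence genes, which is the question the 4 groups address. Each value is a log2 difference from the probe set's own median over the 12 arrays, so changes between groups, but no expression levels, were compared. Array medians lay between -0.0208 and 0.0255, and the number of arrays limits the precision. The 3′ minus 5′ signal of the spiked dap control moved with the replicate number, with means of -0.417 ± 0.247 (SD, n = 4) for number 1, -0.0719 ± 0.253 for number 2 and 1.01 ± 0.114 for number 3. Its group means lay between 0.0961 and 0.291, with an SD of at least 0.641 within each group (n = 3). The actin 3′ minus 5′ signal, which comes from the sample RNA, had means of -0.0918 ± 0.202 (SD, n = 3) in control, -0.236 ± 0.277 in INA, -0.21 ± 0.239 in BLM and 0.0733 ± 0.0583 in BLM+INA. The BLM+INA arrays lay above the 3 BLM arrays and overlapped those of control and INA. Between 3 and 3 arrays, chance gives no overlap, in either direction, in 10% of cases. The GAPDH means were 0.0738, 0.0731, -0.0387 and -0.0834 in the same order. Changes below are log2 values ± SE with n = 3 arrays per group, and p values are those of limma, two-sided and adjusted over 22746 probe sets.

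The first comparison asked what INA alone changed. AT5G03350, of the legume lectin family, rose most among the named genes, by 4.94 ± 0.13 (adjusted p = 3.46e-13), which is 30.6-fold. AT2G41090, a calmodulin-like protein, rose by 3.90 ± 0.17, AT2G25510 by 3.40 ± 0.16, AT1G19960 by 3.27 ± 0.13 and AT2G32160 by 3.16 ± 0.12. Among receptor-like genes, the TIR-NBS gene AT3G04210 rose by 2.51 ± 0.18 and the leucine-rich repeat kinase gene AT1G35710 by 2.45 ± 0.16. AT5G55450, AT1G74440 and AT3G22240 rose by 2.35 ± 0.19, 1.98 ± 0.15 and 1.66 ± 0.11. Falls were smaller: AT1G13650 fell by 1.32 ± 0.18 and DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, fell by 0.99 ± 0.15, with AT1G14960 (-0.95 ± 0.16), AT2G27420 (-0.86 ± 0.11) and AT1G62510 (-0.85 ± 0.15) next.

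In all, 264 probe sets passed the threshold with INA, 207 upward and 57 downward, and 79 of them changed at least 2-fold. The salicylic acid and systemic acquired resistance list shifted upward as a set (mean 0.38, 4 named members, adjusted p = 0.000607), but adjusted p = 0.0523 with an estimated correlation. None of its 4 members passed over all genes tested with limma, against 3 adjusted over the list alone: UGT76B1 stood at 0.50 ± 0.14, WRKY53 at 0.55 ± 0.18, GRXC9 at 0.41 ± 0.13 and SAG101 at 0.04 ± 0.17. The abscisic acid and dehydration list shifted downward (mean -0.31, 3 members, adjusted p = 0.00276; adjusted p = 0.0628 with an estimated correlation), with none of its members past the threshold and 2 adjusted over the list alone; COR15A stood at -0.41 ± 0.13 and COR15B at -0.37 ± 0.14. The other 7 lists tested did not pass with INA, while fry gave 0.00672 for the photosynthesis list (mean -0.06). The count fell to 168 without INA replicate 1, to 169 without control replicate 1, to 172 without the 4 arrays numbered 3 and to 117 without moderated variances.

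The second comparison asked what BLM alone changed. AT5G60250 rose by 4.97 ± 0.13 (adjusted p = 1.99e-13), which is 31.4-fold, DFR by 3.50 ± 0.15 and AT3G12900 by 2.91 ± 0.13. Further rises were those of AT4G36700 (2.58 ± 0.28), AT1G73040 (2.45 ± 0.11), AT3G45730 (2.40 ± 0.21), AT4G14090 (2.33 ± 0.15), AT5G11410 (2.29 ± 0.13), AT4G22960 (2.28 ± 0.12) and AT2G18600 (2.21 ± 0.13). The jacalin-related lectin gene AT1G52070 fell by 3.48 ± 0.24 and its family member AT1G52060 by 2.78 ± 0.16, the peroxidase gene AT4G26010 fell by 2.82 ± 0.17, AT2G33850 fell by 3.21 ± 0.18 and the defensin-like gene PDF2.5 (AT5G63660) fell by 2.70 ± 0.19. AT1G50060 (-2.92 ± 0.17), AT4G22490 (-2.89 ± 0.24), AT3G05600 (-2.85 ± 0.18), AT5G54370 (-2.68 ± 0.27) and AT1G06100 (-2.66 ± 0.15) completed the 10 largest named falls.

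All 3 named members of the G2 and mitosis list fell with BLM (mean -1.17, adjusted p = 3.74e-06): the Aurora kinase genes AUR1 (-1.13 ± 0.11) and AUR2 (-1.50 ± 0.15), and the kinesin gene PAKRP1L (-0.89 ± 0.12). Of the root tissue markers (mean -0.70, adjusted p = 0.00116), the root hair expansin genes EXP7 (-1.21 ± 0.12) and EXP18 (-0.82 ± 0.11) fell, while the root beta-glucosidase gene PYK10 stood at -0.06 ± 0.10. The xenobiotic detoxification list shifted upward (mean 0.48, adjusted p = 0.0173; adjusted p = 0.0737 with an estimated correlation), and 4 of its 6 members rose. UPOX (AT2G21640) rose by 1.59 ± 0.17, GSTU25 by 0.47 ± 0.15, UGT73C1 by 0.39 ± 0.11 and DTX3 by 0.35 ± 0.11. Without 1 array at a time, GSTU25 lost its call in 4 of 12 fits (range 0.31 to 0.63), UGT73C1 in 4 (0.32 to 0.46) and DTX3 in 5 (0.30 to 0.39).

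Of the DNA damage response and repair list, 5 of 40 genes were named, and as a set they did not pass with BLM (mean 0.25, adjusted p = 0.0919). RAD5A, a DNA helicase of damage tolerance, rose by 0.46 ± 0.13 and LIG4, the ligase of DNA end joining, by 0.36 ± 0.10; FAN1 stood at 0.18 ± 0.09 and RAD51B at 0.17 ± 0.12. RAD5A lost its call without control replicate 3 (0.31), BLM replicate 1 (0.41) or BLM replicate 2 (0.41), and LIG4 lost it in 5 of 12 fits (range 0.29 to 0.43). The set passed without control replicate 1 (mean 0.28, adjusted p = 0.0465), and fry, which does not compare a list with other genes, gave 0.00339. The salicylic acid list shifted upward (mean 0.54, adjusted p = 0.0258; adjusted p = 0.175 with an estimated correlation), with WRKY53 (0.84 ± 0.18) and SAG101 (0.80 ± 0.17) past the threshold and 3 members adjusted over the list alone. That set call was lost without control replicate 2 (mean 0.49) or BLM replicate 2 (mean 0.46).

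The abscisic acid list lay lower with BLM (mean -0.43, adjusted p = 0.048; adjusted p = 0.178 with an estimated correlation) through COR15B (-1.02 ± 0.14), with COR15A at -0.26 ± 0.13, and the call was lost without control replicate 1 (-0.44) or 3 (-0.37) or BLM replicate 1 (-0.40) or 2 (-0.44), and with array centring (-0.45) or array weights (-0.40). The endoplasmic reticulum list did not pass (mean -0.15, adjusted p = 0.209; fry gave 0.0259). Its calreticulin gene CRT1B fell by 0.35 ± 0.10, a call lost without control replicate 1 (-0.33) or 2 (-0.31) or BLM replicate 1 (-0.30) or 3 (-0.34). SEC61A (-0.30 ± 0.12), ERDJ3B (-0.27 ± 0.10) and BZIP60 (0.33 ± 0.12) did not pass, but SEC61A passed without control replicate 3 (-0.40) and BZIP60 without control replicate 3 (0.40) or INA replicate 3 (0.33). The pattern-triggered immunity list did not pass either (mean 0.23, adjusted p = 0.636), while fry gave 0.0253. With both agents it did not pass by camera (mean 0.28, adjusted p = 0.401), while fry gave 0.0048. With BLM, its ubiquitin ligase gene PUB23 rose by 0.98 ± 0.15. PUB22 fell by 0.38 ± 0.11, a call lost without control replicate 1 (-0.28) or BLM replicate 1 (-0.34). The photosynthesis list, set as a measure of green shoot tissue, did not pass (mean -0.16, adjusted p = 0.193), while fry gave 2.155e-05. PSAN fell by 0.52 ± 0.09 and the other 3 members did not pass. Over all probe sets, 1905 rose and 1885 fell with BLM, 3790 in all, and 571 of them changed at least 2-fold.

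**Figure D1:**
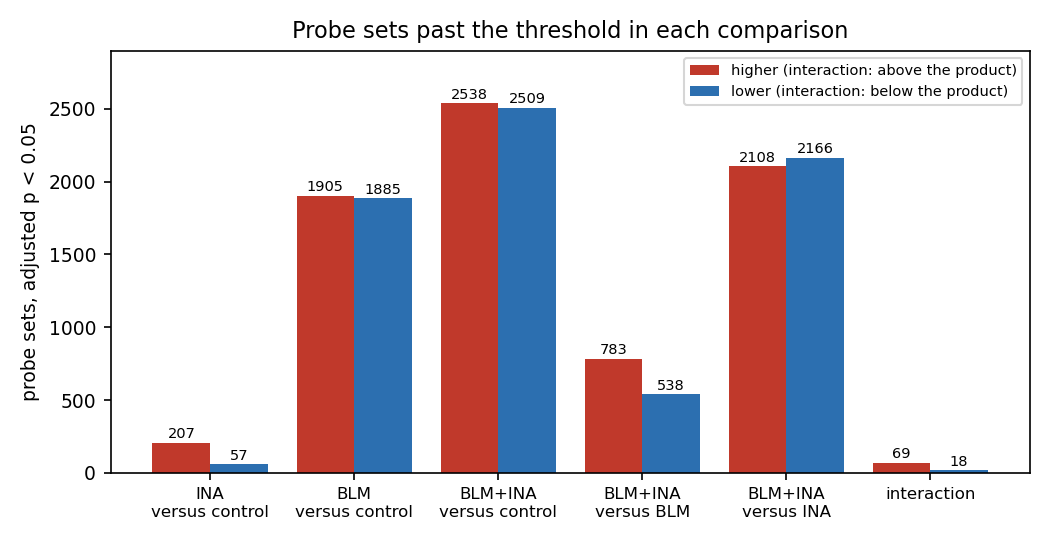
Number of probe sets (vertical axis) past an adjusted p of 0.05 in each of the 6 comparisons (horizontal axis), with red bars for higher and blue bars for lower values, or for changes above and below the product of the single effects in the interaction. Comparisons with BLM in 1 group and not in the other reach 3790 to 5047 probe sets, INA alone 264, and the interaction 87.

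The third comparison asked what both agents together changed. AT5G03350 rose by 5.85 ± 0.13 (adjusted p = 2.03e-14), which is 57.8-fold, AT5G60250 by 4.97 ± 0.13, AT2G41090 by 4.51 ± 0.17, AT1G35710 by 4.39 ± 0.16 and AT5G55450 by 4.34 ± 0.19. AT5G52750 (4.15 ± 0.18), the zinc finger gene STZ (3.78 ± 0.34), AT3G45730 (3.72 ± 0.21), the RING ubiquitin ligase gene RING1 (3.72 ± 0.19) and AT5G52760 (3.70 ± 0.16) followed. The largest named falls were those of AT1G52070 (-3.24 ± 0.24), AT1G13650 (-3.18 ± 0.18), AT4G26010 (-3.17 ± 0.17), AT1G52060 (-2.75 ± 0.16) and AT1G50060 (-2.71 ± 0.17), with AT2G33850, AT3G19430, AT3G05600, AT5G54370 and PDF2.5 between -2.67 and -2.41. In all, 5047 probe sets passed, 2538 upward and 2509 downward, and 896 changed at least 2-fold.

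All 4 named members of the salicylic acid list rose with both agents (mean 1.73, adjusted p = 3.74e-06): the transcription factor gene WRKY53 by 3.52 ± 0.18, SAG101 by 1.36 ± 0.17, the glutaredoxin gene GRXC9 by 1.05 ± 0.13 and the glucosyltransferase gene UGT76B1 by 0.98 ± 0.14. Of the xenobiotic list (mean 0.67, adjusted p = 0.000435), 5 of 6 members rose, led by UPOX (1.62 ± 0.17) and GSTU25 (0.64 ± 0.15). The 3 G2 and mitosis members fell (mean -1.08, adjusted p = 5.72e-05), as did EXP7 (-1.16 ± 0.12) and EXP18 (-1.08 ± 0.11) among the root markers (mean -0.75, adjusted p = 0.00353), with PYK10 at -0.02 ± 0.10. The photosynthesis list did not pass (mean -0.25, adjusted p = 0.0661), while fry gave 2.286e-06. In it, 2 of 4 members fell, PSAN by 0.52 ± 0.09 and LHCB4.2 by 0.28 ± 0.09. LHCB4.2 lost its call in 6 of 12 fits without 1 array (range -0.30 to -0.22). In the abscisic acid list (mean -1.16, adjusted p = 0.0015; adjusted p = 0.0523 with an estimated correlation), COR15B fell by 1.84 ± 0.14 and COR15A by 1.69 ± 0.13, and LTI30 stood at 0.04 ± 0.12. The endoplasmic reticulum list did not pass (mean 0.32, adjusted p = 0.152; fry gave 0.00145): BZIP60 rose by 0.99 ± 0.12, and ERDJ3B (0.21 ± 0.10), SEC61A (0.06 ± 0.12) and CRT1B (0.02 ± 0.10) did not pass. The DNA damage list did not pass (mean 0.19, adjusted p = 0.244; fry gave 0.0131); LIG4 rose by 0.38 ± 0.10, a call lost without control replicate 1 (0.35).

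Lists with fewer than 3 named members were described gene by gene. For jasmonate and ethylene, the defensin gene PDF1.2a (AT5G44420) stood at -0.65 ± 0.26 with INA, -0.63 ± 0.26 with BLM and -0.74 ± 0.26 with both, where its adjusted p was 0.0535 over probe sets and 0.0498 over genes. PDF1.2b stood at -0.77 ± 0.26 with BLM (adjusted p 0.052 over probe sets and 0.0481 over genes). Without control replicate 1, PDF1.2a with both agents stood at -1.05 and PDF1.2b with BLM at -1.16, both past the threshold. For S phase and replication, ICU2 (0.27 ± 0.12) and MCM7 (0.01 ± 0.12) did not pass with BLM. MCM7 was lower with both agents than with INA (-0.47 ± 0.12, adjusted p = 0.0107), a call lost without INA replicate 1 (-0.36). Against control it stood at -0.33 ± 0.12 with both agents (adjusted p = 0.0616), and passed without INA replicate 1 or 3 or BLM replicate 3 (each -0.33) or BLM+INA replicate 1 (-0.42). IGPS, of the camalexin and indole glucosinolate list, rose with both agents by 0.43 ± 0.10. HSP22, of the heat shock list, stood at 0.10 ± 0.09 with both agents, and 0 members of the senescence list were named.

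The comparison of BLM+INA with BLM asked what INA changed on top of BLM. AT5G03350 rose by 3.83 ± 0.13 (adjusted p = 6.39e-12), AT5G55450 by 3.77 ± 0.19, AT1G35710 by 3.70 ± 0.16, AT2G41090 by 3.28 ± 0.17 and AT1G19960 by 3.27 ± 0.13. AT1G62510 fell by 1.70 ± 0.15, AT5G48490 fell by 1.46 ± 0.22, AT1G13650 fell by 1.45 ± 0.18, SAG29 fell by 1.44 ± 0.12 and COR15A fell by 1.43 ± 0.13. The salicylic acid list shifted upward (mean 1.19, adjusted p = 6.79e-08), with WRKY53 (2.68 ± 0.18), GRXC9 (0.89 ± 0.13) and UGT76B1 (0.63 ± 0.14) past the threshold; UGT76B1 lost its call without BLM replicate 1 (0.46) or BLM+INA replicate 1 (0.57). Of 4 endoplasmic reticulum members (mean 0.47, adjusted p = 2.21e-05), the stress transcription factor gene BZIP60 rose by 0.66 ± 0.12, the co-chaperone gene ERDJ3B by 0.48 ± 0.10 and CRT1B by 0.37 ± 0.10, the last with its call lost in 5 of 12 fits without 1 array (range 0.32 to 0.44). CRT1B lay below control with BLM and at 0.02 with both agents, where BZIP60 was the only member of the 4 past the threshold against control. Of 3 abscisic acid members (mean -0.73, adjusted p = 0.0011), COR15A and COR15B (-0.82 ± 0.14) fell and LTI30 stood at 0.06 ± 0.12. The xenobiotic list shifted by 0.19 (adjusted p = 0.0494; adjusted p = 0.131 with an estimated correlation) with 0 of 6 members past the threshold and 2 adjusted over the list alone. It lost its call without BLM replicate 1 (0.14) or 2 (0.20), without BLM+INA replicate 2 (0.20) or 3 (0.15), and after quantile normalization (0.11). In all, 1321 probe sets passed, 783 upward and 538 downward, against 875 without BLM replicate 1 and 831 without moderated variances.

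Relative to INA alone, BLM+INA raised AT5G60250 by 4.57 ± 0.13 (adjusted p = 8.1e-13), AT3G45730 by 3.69 ± 0.21, DFR by 3.11 ± 0.15, AT5G52750 by 3.11 ± 0.18 and WRKY53 by 2.97 ± 0.18. The jacalin-related genes AT1G52070 (-3.15 ± 0.24), AT1G52060 (-2.76 ± 0.16) and AT1G52050 (-2.60 ± 0.14) fell, with AT4G26010 (-2.94 ± 0.17) and AT2G33850 (-2.60 ± 0.18). All 4 salicylic acid members rose (mean 1.35, adjusted p = 2.21e-05), UGT76B1 (0.48 ± 0.14) with its call lost without INA replicate 2 (0.43), INA replicate 3 (0.47) or BLM+INA replicate 1 (0.42). The 3 G2 and mitosis members fell (mean -1.08, adjusted p = 2.21e-05), and so did EXP7 and EXP18 of the root markers (mean -0.65, adjusted p = 0.00436), with PYK10 at 0.01 ± 0.10. The photosynthesis list did not pass (mean -0.19, adjusted p = 0.135), while fry gave 6.257e-06. PSAN fell by 0.38 ± 0.09 and LHCB4.2 by 0.31 ± 0.09, the latter lost without INA replicate 1 (-0.27) or BLM+INA replicate 1 (-0.26). COR15A and COR15B fell (abscisic acid list mean -0.86, adjusted p = 0.00564; adjusted p = 0.0791 with an estimated correlation), and 3 of 6 xenobiotic members rose (mean 0.57, adjusted p = 0.00144). The endoplasmic reticulum list did not pass (mean 0.25, adjusted p = 0.291; fry gave 0.00636), with BZIP60 past the threshold (0.97 ± 0.12). In all, 4274 probe sets passed, 2108 upward and 2166 downward.

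The interaction asked whether the change with both agents departed from the product of the single changes, which is their sum on the log2 scale. Among the named genes, AT5G52760 stood 2.46 ± 0.23 above the sum (adjusted p = 3.02e-05), since it rose by 0.74 ± 0.16 with INA, 0.49 ± 0.16 with BLM and 3.70 ± 0.16 with both. WRKY53 stood 2.13 ± 0.26 above it, AT5G52750 2.1 ± 0.26 and AT5G18470 2.0 ± 0.27. AT3G09020 also stood 2.0 ± 0.18 above it, with 0.06 ± 0.13 for INA, 0.04 ± 0.13 for BLM and 2.1 ± 0.13 for both. AT3G60420 (1.66 ± 0.30), AT3G48650 (1.53 ± 0.20), AT1G24140 (1.49 ± 0.15), AT5G55450 (1.41 ± 0.28) and AT1G10340 (1.39 ± 0.18) followed; a second probe set of AT3G60420 stood at -0.07 and did not pass.

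**Figure D2:**
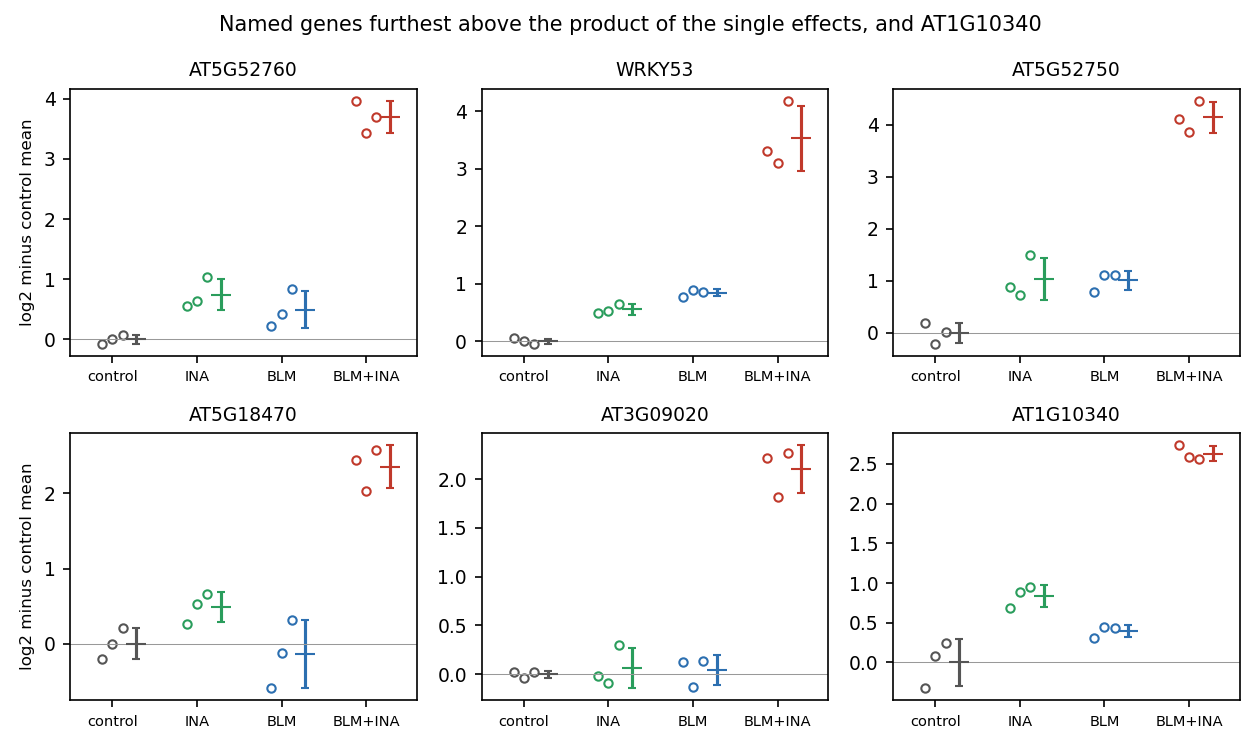
Log2 value minus the control mean (vertical axes) in the 4 groups (horizontal axes) for the 5 named genes furthest above the product of the single effects and for AT1G10340. Circles are arrays (3 per group), with the group mean and SD beside them; in AT5G52760 the BLM+INA mean of 3.70 exceeds the 0.74 of INA and the 0.49 of BLM together.

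Other genes ended below the sum. The probe set furthest below was not named by the gene table and stood at -2.84 ± 0.44 (adjusted p = 0.00511). Among the named genes, AT5G57760 and AT2G25510 both stood at -1.37 (± 0.24 and ± 0.23), AT3G12900 at -1.22 ± 0.19, AT5G03350 at -1.11 ± 0.19, COR15A at -1.02 ± 0.19 and AT5G38820 at -1.01 ± 0.17. AT2G25510 rose by 3.40 with INA, 1.56 with BLM and 3.59 with both, and AT5G03350 rose by 4.94, 2.03 and 5.85. AT3G18560 (-0.91 ± 0.18), AT1G03990 (-0.89 ± 0.16), SAG29 (-0.81 ± 0.16) and AT3G57780 (-0.76 ± 0.15) completed the 10 named genes below the sum. Without 1 array at a time, calls were lost in at least 1 of 12 fits for AT3G18560 (10 fits, range -1.08 to -0.77), AT3G57780 (10 fits, -0.86 to -0.68), SAG29 (9 fits, -0.92 to -0.73), AT5G55450 (6 fits, 1.14 to 1.55) and AT3G60420 (4 fits, 1.49 to 1.88). COR15A lost its call without control replicate 2 (-0.99) or BLM+INA replicate 1 (-0.93). Without the 4 arrays numbered 3, calls were lost for AT5G57760 (-1.49), COR15A (-0.86), AT1G03990 (-0.84), AT3G57780 (-0.84), SAG29 (-0.75) and AT5G55450 (1.54).

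**Figure D3:**
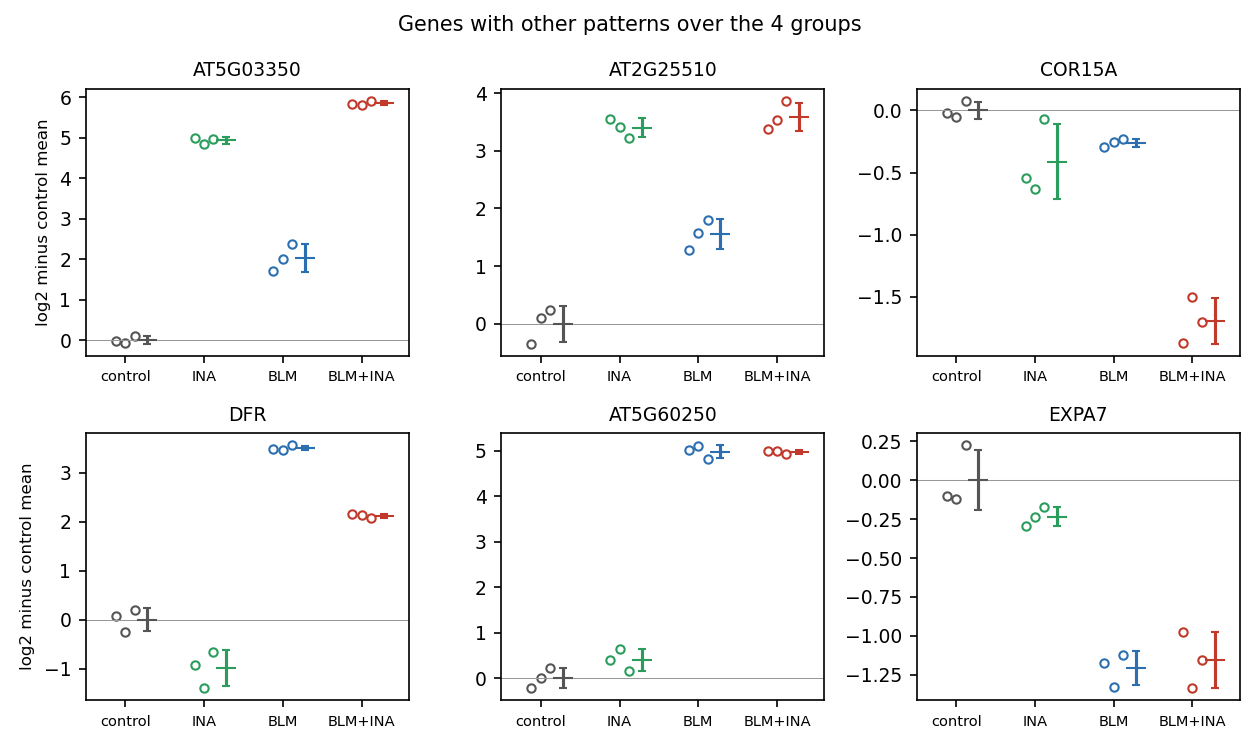
Log2 value minus the control mean (vertical axes) in the 4 groups (horizontal axes) for 6 named genes with other patterns, with circles for arrays (3 per group) and the group mean and SD beside them. DFR lies at 3.50 with BLM and 2.12 with both agents, AT5G60250 at 4.97 in both, and COR15A at -1.69 with both agents.

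The interaction passed for 87 probe sets, 69 above the product of the single changes and 18 below. The 69 had a median change of 1.93 with both agents, against a median sum of single changes of 0.62, and 59 of them rose with both agents, 12 with each single agent too and 22 with neither single agent past the threshold. The actin 3′ minus 5′ signal was highest in BLM+INA too (0.0733 ± 0.0583). That of GAPDH was lowest there (-0.0834), and that of ubiquitin (0.0382) lay below BLM (0.0468), so these signals differ in direction. The salicylic acid list, with 4 of 39 genes named, stood above the sum (mean 0.82, median 0.50, adjusted p = 2.2e-05). With an estimated correlation its adjusted p was 0.0309. WRKY53 (2.13) passed the threshold, and SAG101 (0.52), GRXC9 (0.48) and UGT76B1 (0.13) did not. Adjusted over the list alone, 2 members passed. The endoplasmic reticulum list also stood above the sum (mean 0.40, adjusted p = 0.00011, and 0.0293 with an estimated correlation). None of its 4 members passed the threshold, against 2 adjusted over the list alone. BZIP60 stood at 0.64 ± 0.16 (0.75 and past the threshold without INA replicate 3) and ERDJ3B at 0.41 ± 0.14. The shift of this list reflects in part values below control with BLM (CRT1B -0.35, SEC61A -0.30 and ERDJ3B -0.27). The list did not pass against control with both agents (mean 0.32, adjusted p = 0.152). The abscisic acid list stood below (mean -0.42, adjusted p = 0.0258; adjusted p = 0.14 with an estimated correlation) through COR15A, and lost its call without control replicate 2 (-0.37), INA replicate 3 (-0.32), BLM replicate 2 (-0.41), BLM replicate 3 (-0.39) or BLM+INA replicate 1 (-0.36). The DNA damage (mean -0.12, adjusted p = 0.371), mitosis (0.10, 0.432), xenobiotic (0.09, 0.311), photosynthesis (-0.03, 0.877) and root marker (0.05, 0.632) lists did not pass, nor did pattern-triggered immunity (mean -0.04, median 0.04, adjusted p = 0.877).

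With the replicate number as a block, 170 probe sets passed, 129 above and 41 below, the 87 among them. After quantile normalization of the centred values, 45 probe sets passed, 26 above and 19 below, and 38 of them were among the 87; 13 of the 20 named interaction calls held, with AT5G52760 at 1.39, WRKY53 at 1.21 and AT3G09020 at 1.29. AT5G52750 (1.1), AT5G18470 (1.18), AT3G60420 (0.89), AT5G55450 (0.46), AT1G10340 (0.70), AT3G18560 (-0.87) and AT3G57780 (-0.81) lost theirs, and without moderated variances 2 probe sets passed, with AT1G24140 as the named gene (adjusted p = 0.0236). On the linear scale, where no interaction means that single increments add, 235 probe sets passed, and 79 passed on both scales.

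**Figure D4:**
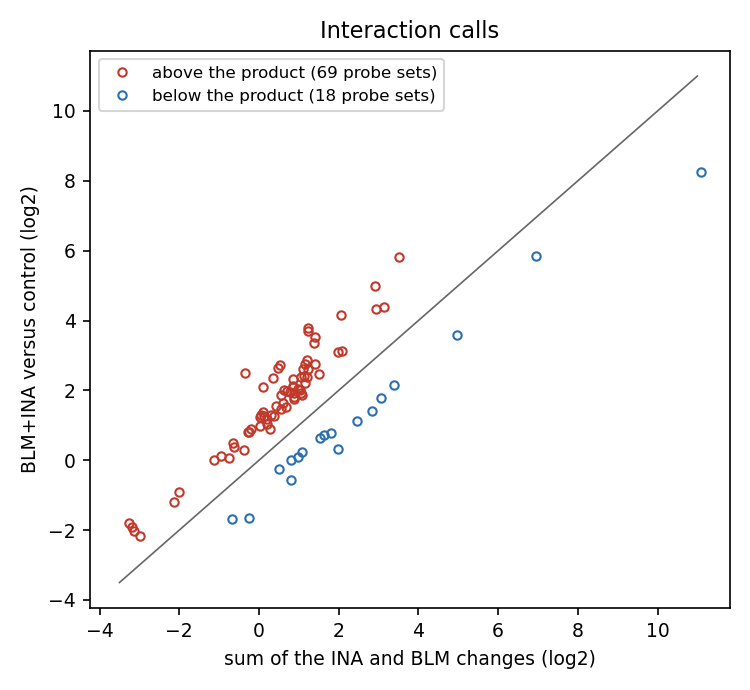
Change with both agents (vertical axis, log2) against the sum of the INA and BLM changes (horizontal axis, log2) for the 87 interaction probe sets, with the line of equality. The 69 red circles lie above the line and the 18 blue circles below it.

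The calls of INA alone and BLM alone overlapped in 166 probe sets, of which 126 rose in both, 21 fell in both and 19 went opposite ways. AT5G03350, AT2G41090 and AT2G25510 rose with each single agent, AT1G13650 and AT1G14960 fell with each, and DFR fell with INA and rose with BLM. Independent lists would give 17.3, 4.72 and 21.9 probe sets. Simulated unchanged groups against the shared controls gave 0, as groups without effects give almost no calls, so that count does not measure what shared controls add to lists of this size. Across probe sets, which are not independent replicates, the covariance of the 2 changes was 0.0185, against 0.00763 in 50 simulations in which the shared controls alone link them, a difference of 0.0109. Pearson r was 0.246, against 0.502 in the simulations. Shared controls without effects give an r near the latter by construction, and changes with 1 agent alone lower it. Nothing is therefore read from the lower r. The 3 controls cannot be divided into groups of at least 2, so part of the overlap may come from the shared controls. The overlap fell to 94 without control replicate 1 and to 66 without moderated variances.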

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

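The tests on the brightest probe sets, of unequal spread and of the 10 probe sets raised most by BLM, and all counts of other splits, were chosen after the result was seen. The intervals of shares, the comparison with array medians, the filter under a level of 4 and the fit without the 4 arrays numbered 3 were chosen after seeing the data.

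The effect of INA differed with and without BLM, by the interaction term, in these named genes (log2): AT5G52760 2.46, WRKY53 2.13, AT5G52750 2.1, AT5G18470 2.0, AT3G09020 2.0, AT3G60420 1.66, AT3G48650 1.53, AT1G24140 1.49, AT5G55450 1.41, AT1G10340 1.39, AT1G35710 1.25 and AT1G14960 1.08. The interaction was negative in AT5G57760 (-1.37), AT2G25510 (-1.37), AT3G12900 (-1.22), AT5G03350 (-1.11), COR15A (-1.02), AT5G38820 (-1.01), AT3G18560 (-0.91), AT1G03990 (-0.89), SAG29 (-0.81) and AT3G57780 (-0.76). AT1G35710 rose with INA, BLM and both, and AT1G14960 fell by 0.95, 1.06 and 0.92, so that its positive interaction reflects falls that did not add. The salicylic acid (mean 0.82), endoplasmic reticulum (0.40, where the means of 3 of 4 members lay below control with BLM) and abscisic acid (-0.42) lists differed as sets by camera; the abscisic acid list lost its call with an estimated correlation (adjusted p = 0.14) and in 5 of 12 fits without 1 array (without control replicate 2, -0.37; INA replicate 3, -0.32; BLM replicate 2, -0.41; BLM replicate 3, -0.39; BLM+INA replicate 1, -0.36). Outside the main measurement, control probe set AFFX-r2-At-U12639_at lay above the control group by 0.85 with INA and 3.57 with BLM+INA (adjusted p = 1.11e-09 over 64 control probe sets), against 0.41 with BLM (adjusted p = 0.162).

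Most interaction calls lay above the product of the single changes, 69 of 87 or 79.3%. The share was 78.9% with each array centred, where 86 of the 87 were kept. Centring could change little, since RMA quantile-normalizes arrays and so leaves their medians close. The array medians give an interaction of -0.016 against at least 0.629 in each call above. This argues against offsets left in the deposited values. The share was 85.5% without the 4 arrays numbered 3 (95% interval 74.2 to 93.1), which argues against these arrays as the source. The intervals of shares treat probe sets as independent, which they are not. They may therefore be too narrow and do not measure variation between arrays. Compression of dim probe sets at the array floor stays open, because 72.7% lay above without probe sets under a level of 4, which passes the 70% set before that test by less than its spread (95% interval 60.4 to 83). By level, 17 of 17 calls lay above under 4, 46 of 56 (82.1%) from 4 to 8 and 6 of 14 (42.9%) at 8 or over. The planned limit of 5 lies within the middle class and could not be applied, and the brightest class holds few calls and may be lowered by saturation. Unequal spread stays open too, with 57.8% above after quantile normalization of the centred values. This narrows the group with the widest values by construction and so cannot tell a technical from a biological spread. Per the labels, RMA had already quantile-normalized the arrays before the centring. The centring removed the levels that would let this be checked. A combined effect of both agents is the biological explanation that the groups name, and it could not be told apart from those 2.

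INA replicate 3 lay above the other INA arrays by a median of 0.226 on 32 interaction probe sets, and on 26 of them it was higher. These were picked for BLM+INA values at least 1.5 above the other INA arrays. That choice favours low values in those arrays, so part of the deviation may come from it. On 65 probe sets raised by BLM alone and picked with the same gap, INA replicate 3 lay higher by a median of 0.262, with 52 above. RNA of a BLM+INA sample in INA replicate 3 would raise BLM genes alike: these 65 probe sets implied a share of 7.64%, against 5.34% from the interaction probe sets. The quartiles of these shares were 0.354% and 15%, and 1.52% and 9%. The 10 raised most implied a median of 2.74% and single shares from -1.03% (AT5G60250, which lay 0.35 lower where a rise of 1.08 was predicted) to 60.3%, with 3 of them at 46.3% or more, so they agree on no single share. The tests disagree and mixing stays open. A deviation of all arrays numbered 3 stays open as well, since their mean in the other 3 groups was 0.107. No biological explanation was tested, and without these 4 arrays 62 interaction calls were left, 47 of them among the 87.

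Of 100 splits of the 12 arrays into 4 groups, 3 gave at least 87 interaction calls, the real one included, and the highest other gave 613. The other 99 each put arrays with and without BLM in 1 group, which raised the median residual SD to between 0.155 and 0.179, against 0.142 for the real split. Low counts are thus built into them, and nothing is read from their share on whether chance gave the 87. The splits with 613 and 397 calls had a contrast that ran along INA with BLM mostly kept within groups, a structure of the samples, and the other 97 gave at most 2. With 3 against 3 arrays, the 10 splits cannot give a share under 0.05. In each of the 5 comparisons, 1 split, the real one, gave the most calls: 264 for INA (highest other 5), 3790 for BLM (0), 5047 for BLM+INA (0), 1321 against BLM (1) and 4274 against INA (0).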

How the results depend on the processing

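The level filter from number spacing and the fits without the 4 arrays numbered 3 were chosen after seeing the data; the planned filter on a mean level under 5 and the variance trend were not run. Of 167 alternative counts, 135 stayed within 1.5 times the reported one; of 1026 list alternatives 982 kept direction and side of the threshold, 30 were weaker and 14 stronger; of 6721 for named genes, 6489 kept both, 180 were weaker and 52 stronger, and 0 reversed in either. Counts in the order INA, BLM, BLM+INA, against BLM, against INA, interaction and overlap follow. With 1-gene probe sets they were 110, 1937, 2583, 650, 2121, 38 and 64, as fewer were tested. With a 2-fold minimum they were 79, 571, 896, 248, 632 and, for the overlap, 26. At an adjusted p of 0.01 they were 158, 2254, 3352, 694, 2569, 42 and 86. Without moderation, INA gave 117, against BLM 831, the interaction 2 and the overlap 66. Without the arrays numbered 3, INA gave 172, as fewer arrays entered, and of 324 named changes 21 lost their call, 6 of them in the interaction, and 2 gained one. The interaction gave 45 after quantile normalization, 170 with the replicate block and 235 on the linear scale. The other counts with the replicate block were 356, 4530, 5762, 1761, 5019 and, for the overlap, 225. No label gives the numbers a meaning and they do not pair all arrays, since deviations from the group means correlated over 0.1 in 10 of 18 same-numbered pairs: from -0.0534 to 0.0796 for number 2, 0.0532 to 0.221 for number 1 and 0.233 to 0.405 for number 3. Only 4 arrays correlated best with their own number in all other groups. The arrays numbered 3 correlated at -0.357 to -0.0388 with those of other numbers, so they deviate together. Without 1 array, INA ranged from 168 (without INA replicate 1; 169 without control replicate 1) to 274, against BLM from 875 (without BLM replicate 1) to 1343, and the overlap from 94 (without control replicate 1) to 173. The salicylic acid list with INA (0.38) had an adjusted p of 0.0523 with an estimated correlation and with BLM (0.54) 0.175; without 1 array the latter ranged from 0.46 to 0.61, lost without control replicate 2 (0.49) or BLM replicate 2. The DNA damage list passed with fry in BLM (0.25, adjusted p 0.00339) and BLM+INA (0.19, 0.0131), and without 1 array ranged from 0.23 to 0.28 in BLM. Where no cause is given, the cause was not tested. Dim probe sets, near the background signal, limit what the interaction shows: 17 of its calls lay under a level of 4.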

Other observations

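The anthocyanin and family lists, the unnamed probe sets and the root tissue test were chosen after the result was seen. The family lists group genes only by the leading letters of their symbols, so a list such as RPS may hold unrelated genes. The 5 genes of anthocyanin synthesis were picked after DFR and AT4G14090 had been seen among the largest rises with BLM, so no set p is given; each of the 5 rose with BLM (mean 2.04) and was lower with BLM+INA than with BLM (mean -1.15) by its own test. DFR rose by 3.50 with BLM and 2.12 with both agents, AT4G14090 by 2.33 and 1.2, UF3GT by 2.15 and 0.85, and AT5MAT by 1.66 and 0.45. UGT78D2 rose by 0.55 with BLM and stood at -0.14 with both. With INA alone, DFR and AT5MAT fell (mean of the 5 -0.54), AT5MAT with its call lost in 4 of 12 fits without 1 array (-0.77 to -0.55). In the interaction, 0 of the 5 genes passed (mean -0.60), so a departure from the sum of the single changes was not shown for any of them. Of the expansin family EXPA, 4 of 10 genes fell with BLM (mean -0.40). It holds EXP7 and EXP18, already seen to fall, so no set p is given. Of the XTH family 4 of 9 fell and 1 rose (mean -0.43, camera adjusted p = 0.0195 over 186 tests, and 0.366 with an estimated correlation). The RPS family passed with BLM too (mean -0.25, adjusted p = 0.0443, and 0.703 with an estimated correlation). The PUB, IQD and TRM families passed in other comparisons. No family call held with an estimated correlation.

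For 9233 of the tested probe sets (40.6%) the gene table gave no single gene, with 503 paired with several and 8730 not in it. The latter may still measure a single gene. Among the 20 largest changes, unnamed probe sets were 13 with INA, 15 with BLM+INA and 16 against BLM. They were 11 each with BLM, against INA and in the interaction. The probe set that changed most with INA rose by 8.01 ± 0.31 with INA, 3.07 ± 0.31 with BLM and 8.25 ± 0.31 with both. Its interaction of -2.84 ± 0.44 (adjusted p = 0.00511) was the lowest of the 87 calls, and passed in all 12 fits without 1 array (-3.42 to -2.51). Another unnamed probe set ranked 4 by size of change with both agents, where it rose by 6.01 ± 0.59. It stood at 1.86 ± 0.59 with INA (adjusted p = 0.23, SD 1.96 between arrays) and 0.73 ± 0.59 with BLM. Its interaction of 3.41 ± 0.83 did not pass (adjusted p = 0.113), but passed without INA replicate 3 (4.55, adjusted p = 1.52e-06).

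A smaller share of root tissue could lower the root hair genes with BLM. EXP7 and EXP18 fell, but PYK10 changed by -0.0631 (95% interval -0.277 to 0.151), which would argue against it. PYK10 lay in the brightest class of probe sets, where saturation may hide a fall, so this stays open.

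A hypothesis was that BLM enlarges the response of genes that INA raises. Over the 207 probe sets that rose with INA alone, the INA change was larger with BLM by a median of 0.197, above 0 in 142. The median was 0.268, 0.117 and 0.199 on the 3 BLM+INA arrays, although selection on the INA change pulls this below 0. These 3 values share the same BLM, INA and control means and are not independent. The reverse hypothesis, that INA enlarges the rise of genes that BLM raised, was not borne out: the median over 1905 probe sets was -0.0976, above 0 in 669, a sign that selection gives as well, so a weaker response was not shown either. Both hypotheses were read from the same interaction term, over different probe sets. Among probe sets that fell, the medians were 0.123 for the 57 of INA and 0.0982 for the 1885 of BLM. The enlarged INA response may share the open sources of the interaction calls, such as unequal spread. Quantile normalization of the centred values (57.8% above the product) cannot decide this, since it narrows the group with the widest values by construction.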
